A study of Mus musculus with 20 samples.

How the data were processed

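Blood RNA of 20 female C57BL/6J mice, 5 in each of 4 groups (2 or 24 months of age, 0 or 4 Gy of x-rays, collected 24 h later), was measured on 1-colour Agilent mouse arrays. Blood was drawn by cardiac puncture at euthanasia into PAXgene solution, and Cy3-labelled cRNA was made from 0.5 ug of RNA. The authors scanned the arrays and extracted them with Agilent Feature Extraction 12.0.2. The deposited scanner files hold, per the file headers, a processed signal in intensity units with spatial and multiplicative detrending on and local background correction off, a surrogate value where a spot was not above background, and no normalization between arrays. The mean signal and median background signal, also intensity values, were used for one alternative. The authors' own values, deposited as log2, cover 14382 probes. Against log2 of the same array's scanner signal they gave r of 0.988 to 1.000, which bore out their scale and direction. The median offset ran from -0.91 to 1.64, so their centring and filter stay unknown, as do the tools used. Their column medians ran from 5.18 to 5.76.

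Each array held 44397 spots, 43020 of them other than controls, for 39429 probes. None was at or below 0 and none was saturated. Control spots and those the scanner software marked as outliers (77 to 237 per array) were left out, and spots of one probe were averaged. The signal was taken as log2 and each array's 75th percentile was subtracted. Probes well above background on at least 4 of 5 arrays in at least 1 group were kept (21096), and the probe of highest mean over all arrays stood for its gene, which left 16548 genes and 30 missing cells. Genes were named by accession for 28663 probes, by symbol for 3300, by synonym for 160 and by the file's own name for 7306. Probes of one gene disagreed in sign among the genes named here for Hmox1 in unirradiated mice of different age (-0.14 and 1.62), Cdkn1a (-0.03 and 0.88, and -0.11 and 0.53 after irradiation) and Klrb1 after irradiation (-1.48 and 0.38). Probes of one sign lay over 1 log2 unit apart for Gzmk in both age comparisons, Cdkn1a (3.91 and 5.05) and Cd34 (2.26 and 0.73) after irradiation in young mice, Cd247 in old mice (1.89 and 0.52) and Csf1r in the interaction (-1.71 to -0.49). Coordinates are those of the mm9 (NCBI37) probe annotation, and exon structure was not used. Replicate probes had a median coefficient of variation of 4.43% to 7.04% per array, highest on the dim array. The spike-in slope was 0.939 to 1.03.

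One model with 4 group means was fitted to all 20 arrays with lmFit and eBayes (limma 3.58.1 in R 4.3.3, with data.table in version 1.17.8). Its 5 contrasts were irradiation in young and in old mice, age in unirradiated and in irradiated mice, and the interaction, each adjusted by Benjamini-Hochberg and called at an adjusted p under 0.05. All p-values of genes come from limma. The main settings, 32 gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took the 7 largest increases and 7 largest decreases per comparison among called genes whose groups did not overlap and whose probe was well above background on all 5 arrays of the higher group (5 and 5 for the interaction, with no overlap rule). It added 14 sentinel genes and up to 3 called members per called list. Clone, locus, predicted and RIKEN names were left out. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, with a smallest size of 5. Mean levels of 13 cell type lists were compared by an exact permutation test over 252 assignments. They are marker levels and not cell counts. Lists share genes: 13 of 42 p53 target genes, 9 of 32 effector genes, 9 of 44 apoptosis genes, 8 of 28 NK cell genes and 7 of 51 phagocytosis genes stand in another list as well.

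Lists of hepatocyte (28 genes, 27 tested), heart muscle (14, 5), lung epithelium (11, 6), mesothelial (16, 13) and body cavity macrophage genes (17, 17) were written after such transcripts had been seen. Heart muscle and lung epithelium lists had no called gene in any comparison. Macrophage genes are also expressed by blood monocytes.

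The alternatives were normexp background correction (offset 50), quantile normalization, scaling over probes well above background on all arrays, no filter on dim probes, only probes well above background on all arrays, a floor on dim values, every probe kept, slide as a fixed or random block, the replicate number as a block, only the arrays compared, array weights, trended and robust variance, the authors' values, camera with an estimated correlation, fry (which tests only whether a list's genes move one way on balance), the median of list members, a 2-fold threshold, an unadjusted p of 0.001 and leaving out each array in turn. Added after seeing the data were a linear model of 3 list levels with slide as a block, and fits without the 5 arrays whose hepatocyte score lay above 2, without those and the dim array, with the hepatocyte score as a covariate, and with hepatocyte, heart muscle, mesothelial and body cavity macrophage scores as covariates. Other splits of the arrays were drawn 100 times with seed 1.

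Replicate numbers were checked for pairing. In young mice all 5 same-numbered pairs of unirradiated and irradiated arrays correlated over 0.1 in their deviations from the group means (0.143 to 0.812). For only 1 of 5 unirradiated arrays was the same-numbered irradiated array also the best correlated one. The numbers were still taken to pair them, and irradiation calls the paired fit ended are given as paired. The labels name no shared litter or day. On simulated data the model recovered 29, 29, 31, 31 and 6 of 100 genes changed 2-fold, in the order above. Of 100 changed 4-fold it found 74, 66, 71, 75 and 47, with 1 to 6 unchanged genes called. A p53 list shifted by log2 1 was always recovered, with 1 of 27 other lists called, only in old mice. This need not hold if genes correlate.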

Results

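Blood gene expression was measured on 1-colour Agilent arrays in female C57BL/6J mice aged 2 (young) or 24 months (old). They were unirradiated or exposed to 4 Gy of x-rays 24 h before collection. The 4 groups held 5 arrays each, 20 in all, and the mice came from independent experiments. The 75th percentile of the signal lay between 97.5 and 242 intensity units on 19 arrays and at 19.7 on old irradiated replicate 5, called the dim array here. On the dim array 33.3% of spots were well above background, against 48.2% to 57.9% on the others. The arrays lay on 5 slides of 4, of which slide 2 held both young groups, slide 3 young irradiated and old unirradiated mice and slide 4 both old groups. No slide held both groups of an age comparison. Levels are log2 intensities relative to the 75th percentile of the array, as mean ± SD of 5 arrays, and log2 fold changes are given ± SE from limma. Where a probe was not well above background on any array of a group, the fold is a lower bound: the brighter group's mean over all 5 arrays against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

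Gene lists fixed beforehand are given with the number of tested members that passed over all 16548 genes and, separately, adjusted over the list alone. Their median log2 fold change is followed by its value with slide as a block (blocked) and by the camera adjusted p with its range over the alternatives. Of the 77 list results that passed the camera test, 10 also passed with an estimated correlation between genes, and for 56 that setting gave the highest adjusted p of all alternatives. For irradiation the blocked value rests on slide 2 in young and slide 4 in old mice. For age, which has no within-slide value, it joins slide 3 to one of these. Blocked signs are no separate test, as both fits share arrays. An exact permutation p of 0.00794 is the smallest that 5 against 5 arrays can give.

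The first comparison asked what changed in young mice 24 h after x-rays. Targets of the DNA damage regulator p53 and genes induced by interferon rose. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 15.1-fold from -1.92 ± 1.10 to 2.00 ± 0.60, a log2 fold change of 3.91 ± 0.44 (adjusted p = 8.74e-06). Slfn4, a Schlafen gene of myeloid cells, rose 53.1-fold (5.73 ± 0.55), and Ifit3, an interferon-induced gene, 29.2-fold (4.87 ± 0.36), although the near-identical Ifit3b makes the gene uncertain. Fcer2a, the low-affinity IgE receptor CD23 of B cells, fell 19.2-fold (-4.27 ± 0.50, adjusted p = 1.38e-05). The probe of Cdkn1a lay on chromosome 17 from 29237377 to 29237436 of the mm9 build and that of Fcer2a on chromosome 8 from 3682343 to 3682402.

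Of 37 p53 target genes, 23 rose and none fell (25 and 1 adjusted over the list alone), with a median log2 fold change of 1.12, 1.35 blocked (camera adjusted p = 1.81e-11, range 1.16e-15 to adjusted p = 6.68e-05 with an estimated correlation). Phlda3, a repressor of Akt signalling, rose 12.8-fold, the death effectors Bax 3.65-fold and Bbc3 3.94-fold, and Ccng1, a cyclin, 4.53-fold. Mdm2, the ubiquitin ligase that degrades p53, rose 2.33-fold (1.22 ± 0.33, adjusted p = 0.0112), and Psrc1, a spindle protein, at least 11.7-fold. Among 42 apoptosis genes, 9 of which stand in other lists too, 17 rose and 1 fell (19 and 1 adjusted over the list alone). Their median was 0.46, 0.53 blocked (camera adjusted p = 4.58e-05, range 7.31e-07 to adjusted p = 0.171 with an estimated correlation). Fasl, a death ligand, rose 4.75-fold. Among 25 senescence and secretory phenotype genes, 11 rose and none fell (13 rose adjusted over the list alone). Their median was 1.09, 0.98 blocked (camera adjusted p = 1.54e-05, range 3.38e-08 to 0.0253, adjusted p = 0.00443 with an estimated correlation). They included Spp1, which encodes osteopontin and was measured on 1 of 5 unirradiated arrays (2.82 ± 0.46). The 39 DNA repair genes passed as a group in the other direction, with a median of -0.37, -0.31 blocked (camera adjusted p = 0.0107, range 0.000711 to adjusted p = 0.401 with an estimated correlation). Of these, 2 rose and 1 fell (2 rose adjusted over the list alone), the latter being Xrcc6, the end-joining protein Ku70 (-0.56 ± 0.18, adjusted p = 0.0282, 0.0907 paired).

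Lymphocyte genes moved apart. Of 25 B cell markers, 18 fell and none rose (22 fell adjusted over the list alone). The list's median was -1.77, -1.84 blocked (camera adjusted p = 3.66e-12, range 1.21e-21 to adjusted p = 0.179 with an estimated correlation). Vpreb3 fell 13.1-fold and Cr2, a complement receptor, 11.7-fold, while Ms4a1, which encodes CD20, missed the threshold (-1.51 ± 0.63, adjusted p = 0.104). The mean level of the B cell list was 2.83 ± 0.441 before and 0.904 ± 0.423 after irradiation (exact permutation p = 0.00794, adjusted p = 0.0206). Of 11 MHC class II genes, 9 fell and none rose (11 fell adjusted over the list alone), with a median of -1.56, -1.63 blocked (camera adjusted p = 4.17e-07, range 1.75e-10 to adjusted p = 0.207 with an estimated correlation), among them H2-Ob (-2.65 ± 0.44). Of 19 naive T cell genes, 2 rose and 10 fell (2 and 11 adjusted over the list alone). The median was -1.32, -1.51 blocked (camera adjusted p = 1.72e-05, range 5.19e-10 to adjusted p = 0.179 with an estimated correlation). Dapl1 fell 18.7-fold and the homing receptor Ccr7 5.38-fold. The T cell markers did not pass as a group (adjusted p = 0.1): Cd8a fell 5.74-fold, and Cd3e of all T cells was at -0.23 ± 0.43 (adjusted p = 0.76). Of 27 NK cell and cytotoxic genes, 25 rose and none fell (26 rose adjusted over the list alone). Their median was 1.73, 1.69 blocked (camera adjusted p = 3.66e-12, range 4.53e-18 to adjusted p = 0.208 with an estimated correlation). The granule protease Gzmb rose 6.21-fold and the NK receptor Ncr1 4.19-fold. Of 31 effector, memory and exhaustion genes of T cells, 9 of them in other lists, 16 rose and none fell (18 rose adjusted over the list alone). Their median was 1.04, 1.12 blocked (camera adjusted p = 1.81e-07, range 1.36e-10 to adjusted p = 0.242 with an estimated correlation).

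Mature neutrophil, monocyte and platelet genes rose. Of 31 mature neutrophil markers, 27 rose and 1 fell (27 and 1 adjusted over the list alone). The members' median was 2.12, 1.91 blocked (camera adjusted p = 4.26e-20, range 3.94e-30 to adjusted p = 0.0995 with an estimated correlation). They included Ly6g (1.71 ± 0.29), the surface protein that defines mouse neutrophils, and Stfa1, a stefin from a family of near-identical genes (3.24 ± 0.40). Of 35 platelet and megakaryocyte genes, 32 rose and none fell (34 rose adjusted over the list alone). The median was 1.98, 1.83 blocked (camera adjusted p = 2.86e-22, range 1.44e-34 to adjusted p = 0.167 with an estimated correlation). The platelet tubulin Tubb1 rose 7.28-fold and the chemokine Pf4 2.32-fold. Of 28 monocyte and macrophage markers, 11 rose and none fell (14 rose adjusted over the list alone). Their median was 0.83, 0.57 blocked (camera adjusted p = 2.03e-06, range 4.4e-09 to adjusted p = 0.171 with an estimated correlation). The Fc receptors Fcgr4 (2.05 ± 0.17) and Fcgr1 (1.94 ± 0.23) rose, and Csf1r, the receptor of macrophage colony-stimulating factor, missed the threshold (0.61 ± 0.25, adjusted p = 0.0901). Of 14 haematopoietic progenitor genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone). Their median was 0.79, 0.78 blocked (camera adjusted p = 0.0127, range 3.1e-06 to 0.303, adjusted p = 0.179 with an estimated correlation). They included Cd34 and Gata2, which rose 4.8-fold and 4.02-fold.

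The interferon-stimulated genes moved in a single direction: of 45, 37 rose and none fell (38 rose adjusted over the list alone). The list's median was 2.00, 1.97 blocked (camera adjusted p = 4.06e-28, range 8.26e-48 to adjusted p = 0.000631 with an estimated correlation). Ifit1 rose 11.9-fold and Rtp4 10.5-fold, and the list's mean level went from 0.773 ± 0.0857 to 2.67 ± 0.198. Of 28 inflammatory cytokine and NF-kB genes, 12 rose and 2 fell (15 and 2 adjusted over the list alone). The median was 0.91, 0.80 blocked (camera adjusted p = 0.000363, range 1.79e-05 to adjusted p = 0.265 with an estimated correlation). The cytokine Il1b rose 5.22-fold. Of 49 phagocytosis and dead cell clearance genes, 23 rose and none fell (23 rose adjusted over the list alone). Their median was 1.01, 0.65 blocked (camera adjusted p = 6.07e-08, range 1.31e-10 to adjusted p = 0.0177 with an estimated correlation). The scavenger receptor Marco rose 7.57-fold (adjusted p = 0.0457, 0.131 without young unirradiated replicate 3), and the bridging protein Gas6 6.03-fold. Genes of other tissues moved with this group: 9 of 13 mesothelial and 3 of 17 body cavity macrophage genes rose, with medians of 3.03 and 1.05 (3.65 and 0.48 blocked). Of 29 proteasome and unfolded protein response genes, 6 rose and none fell (6 rose adjusted over the list alone), among them Chac1 (1.76 ± 0.34) and Ddit3 (1.18 ± 0.30), with a median of 0.37, 0.46 blocked (camera adjusted p = 0.00547, range 0.000796 to 0.265, adjusted p = 0.251 with an estimated correlation). Of 47 ribosomal protein genes, 2 fell over all genes, Rps15 and Rps3 (paired adjusted p = 0.110 and 0.0639), and none adjusted over the list alone, with a median of -0.37, -0.42 blocked (camera adjusted p = 1.41e-05, range 2.56e-08 to adjusted p = 0.506 with an estimated correlation) and of 0.13 with 4 tissue scores as covariates.

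Among the 14 lists that did not pass in young mice were erythroid (7 of 45 rose and 4 fell, adjusted p = 0.0941), oxidative stress response (7 of 26 rose, adjusted p = 0.1), eosinophil and basophil (7 of 19 rose and 1 fell, adjusted p = 0.144), dendritic cell (2 of 18 rose and 2 fell, adjusted p = 0.183, although the level fell from 1.38 ± 0.188 to 0.843 ± 0.215 with an exact permutation p of 0.00794, adjusted p = 0.0206) and FGF signalling genes (6 of 21 rose, adjusted p = 0.279). Endothelial and fibroblast, plasma cell, oxidative phosphorylation, synaptic and muscle genes did not pass either (adjusted p = 0.304, 0.304, 0.409, 0.514 and 0.763). Median and mean differed in sign for cell cycle (0.01 and -0.12, adjusted p = 0.401), immature neutrophil granule (0.33 and -0.00, adjusted p = 0.758) and heat shock genes (-0.01 and 0.18, adjusted p = 0.952).

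In young mice 3357 of 16548 genes passed limma's test at an adjusted p under 0.05, 2541 higher and 816 lower after irradiation, 2453 of them at least 2-fold. With slide as a block, which rests on the 4 arrays of slide 2, 100 genes passed, 73 higher and 27 lower. Of the 3357, 3353 kept their sign. With the scale taken over probes well above background on all arrays, 1742 genes were higher and 2402 lower, and with the authors' own values 1503 and 900. Without the dim array the count was 5042.

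**Figure D1:**
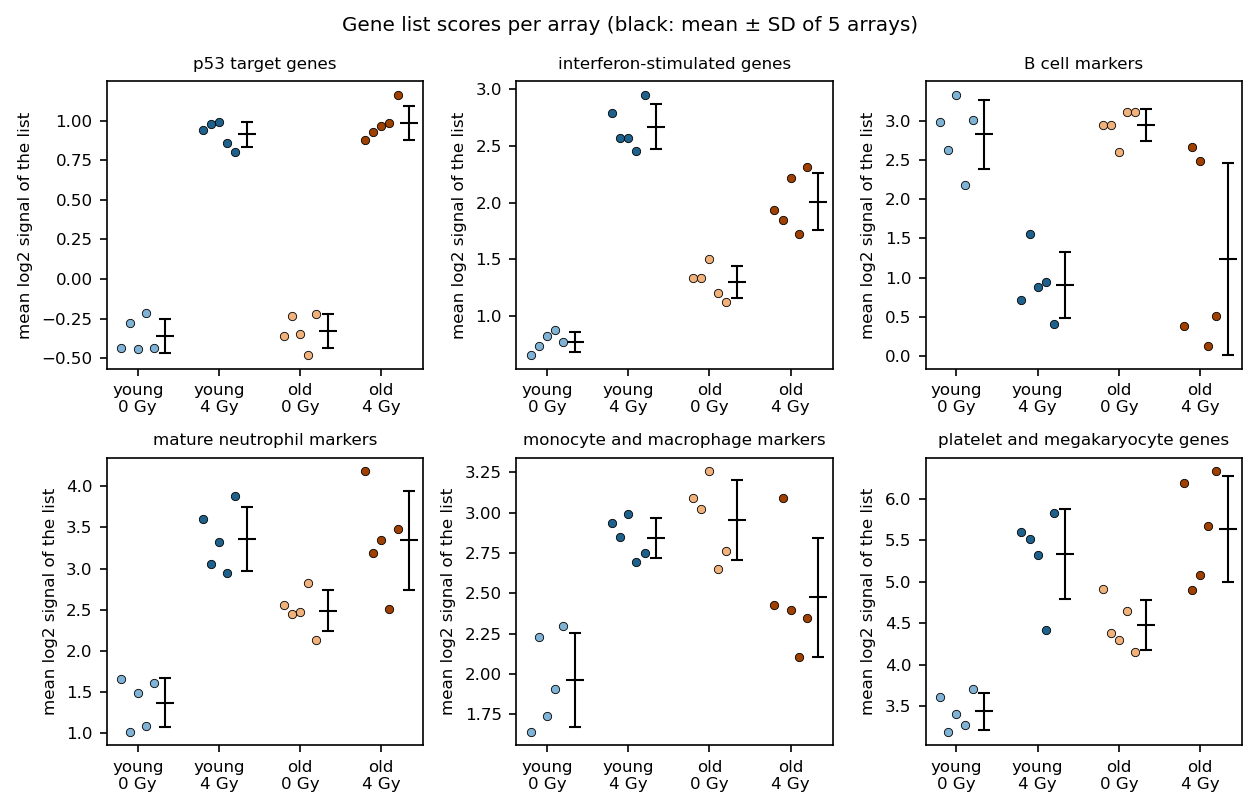
Mean log2 level per array of 6 gene lists (p53 target genes, interferon-stimulated genes, B cell, mature neutrophil and monocyte markers, platelet genes), relative to the 75th percentile of the array. Points are arrays, and bars show the mean ± SD of the 5 arrays of each group. The p53 score lay at -0.361 ± 0.107 and 0.913 ± 0.0815 in young and at -0.327 ± 0.108 and 0.984 ± 0.109 in old mice.

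The second comparison addressed the same exposure in old mice. p53 targets rose here too. Cdkn1a rose 14.2-fold from -1.94 ± 0.27 to 1.89 ± 0.68 (3.83 ± 0.44, adjusted p = 5.23e-05), Phlda3 4.06-fold (2.02 ± 0.21) and Bax 2.72-fold. Marco rose 47.7-fold from -1.28 ± 1.45 to 4.30 ± 1.13 (adjusted p = 0.00319) and Saa3, an acute phase protein, 37.8-fold (adjusted p = 0.0047). Gdf15, a stress cytokine and p53 target, rose by 5.09 ± 0.95 (4.45 without the dim array) and was measured on 1 of 5 unirradiated arrays. Fcer2a fell 26.1-fold (-4.71 ± 0.50, adjusted p = 2.91e-05), measured on 3 of 5 irradiated arrays, and Vpreb3 24.3-fold.

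Of 37 p53 target genes, 21 rose and 1 fell (23 and 1 adjusted over the list alone). Their median was 1.30, 1.12 blocked (camera adjusted p = 4.68e-16, range 3.44e-23 to adjusted p = 5.42e-06 with an estimated correlation). Of 25 B cell markers, 9 fell and none rose (18 fell adjusted over the list alone). The members' median was -1.44, -2.55 blocked (camera adjusted p = 1.24e-13, range 6.37e-25 to adjusted p = 0.199 with an estimated correlation). Of 11 MHC class II genes, 7 fell and none rose (10 fell adjusted over the list alone). The median was -1.61, -2.23 blocked (camera adjusted p = 1.09e-08, range 1.7e-13 to adjusted p = 0.199 with an estimated correlation). H2-Aa, an antigen-presenting chain, fell 4.08-fold. Of 18 dendritic cell markers, 6 fell and none rose (2 and 8 adjusted over the list alone). Their median was -0.65, -0.90 blocked (camera adjusted p = 0.00107, range 2.85e-06 to adjusted p = 0.199 with an estimated correlation). The growth factor receptor Flt3 fell 4.07-fold, measured on 4 of 5 irradiated arrays. Of 28 monocyte and macrophage markers, 10 fell and none rose (2 and 15 adjusted over the list alone). Their median was -0.66, -0.94 blocked (camera adjusted p = 2.54e-05, range 3.08e-10 to adjusted p = 0.225 with an estimated correlation). The chemokine receptor Ccr2 fell 3.66-fold (-1.87 ± 0.27, adjusted p = 0.000665) and the nuclear receptor Nr4a1 2.87-fold, while Csf1r was at -0.74 ± 0.25 (adjusted p = 0.078). Ms4a1 (-1.34 ± 0.63, adjusted p = 0.216) and Cd8a (-0.04 ± 0.49, adjusted p = 0.976) did not pass, and the interaction test of Cd8a missed its threshold as well (2.49 ± 0.69, adjusted p = 0.0747).

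Of 35 platelet and megakaryocyte genes, 15 rose and none fell (30 rose adjusted over the list alone). The list's median was 1.18, 1.88 blocked (camera adjusted p = 8.6e-18, range 2.97e-25 to adjusted p = 0.199 with an estimated correlation). Thbs1, which encodes thrombospondin, rose 3.83-fold, and the integrin Itgb3 3.22-fold. Of 31 mature neutrophil markers, 11 rose and none fell (17 rose adjusted over the list alone), with a median of 0.76, 1.69 blocked (camera adjusted p = 1.52e-09, range 1.57e-21 to adjusted p = 0.282 with an estimated correlation), Slpi among them (1.86 ± 0.33). Of 45 interferon-stimulated genes, 12 rose and none fell (21 and 1 adjusted over the list alone). The median was 0.60, 0.48 blocked (camera adjusted p = 2.23e-11, range 1.95e-13 to adjusted p = 0.0343 with an estimated correlation). Ifit3 rose 5.94-fold (2.57 ± 0.36) and Lgals3bp 3.94-fold. Of 31 effector, memory and exhaustion genes, 3 rose and 1 fell (7 and 1 adjusted over the list alone). Their median was 0.87, 1.27 blocked (camera adjusted p = 1.09e-05, range 5.53e-08 to adjusted p = 0.399 with an estimated correlation). The NK cell and cytotoxic list passed with no called member among 27, at a median of 0.65, 1.58 blocked (camera adjusted p = 0.000367, range 7.99e-13 to adjusted p = 0.545 with an estimated correlation). Of 25 senescence and secretory phenotype genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone). Their median was 0.66, 0.88 blocked (camera adjusted p = 0.000902, range 2.76e-05 to 0.266, adjusted p = 0.0343 with an estimated correlation).

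Of 49 phagocytosis and dead cell clearance genes, 11 rose and none fell (18 and 2 adjusted over the list alone). The members' median was 0.25, 0.75 blocked (camera adjusted p = 0.000902, range 7.49e-05 to 0.998, adjusted p = 0.199 with an estimated correlation). C1qc, a complement subunit made by macrophages, rose 13-fold and Gas6 11-fold. Of 13 endothelial and fibroblast genes, 3 rose and none fell (6 rose adjusted over the list alone). The median was 1.35, 1.62 blocked (camera adjusted p = 0.000367, range 2.81e-05 to 0.964, adjusted p = 0.313 with an estimated correlation). They included the matrix genes Dcn (4.17 ± 1.07, adjusted p = 0.0244, 0.0769 without old unirradiated replicate 3) and Col3a1 (3.14 ± 0.81), measured on 4 and 3 of 5 irradiated and 3 and 1 of 5 unirradiated arrays. Transcripts of other tissues moved with both groups: 9 of 13 mesothelial genes rose (median 2.73, 2.96 blocked) and 9 of 17 body cavity macrophage genes (median 3.07, 2.55 blocked), and the mean cavity macrophage score went from -1.07 ± 0.39 to 1.75 ± 0.82 (exact permutation p = 0.00794). The hepatocyte level went from -5.01 ± 0.39 to -2.44 ± 3.34 (exact permutation p = 0.00794, adjusted p = 0.0127), although none of 27 genes was called (median 2.55, -0.01 blocked). The T cell list passed with 2 of 28 members rising, Cd247 and Lat, at a median of 0.39, 0.91 blocked (camera adjusted p = 0.0192, range 1.21e-09 to adjusted p = 0.695 with an estimated correlation), and lost the call without old unirradiated replicate 1 or 4 (adjusted p = 0.0594 and 0.0518) or old irradiated replicate 1 or 4 (0.157 and 0.288). The ribosomal list, with none of 47 called and a median of -0.19, -0.52 blocked (camera adjusted p = 0.00688, range 2.28e-10 to 0.964, adjusted p = 0.692 with an estimated correlation), lost it without old unirradiated replicate 1 (0.0508) or old irradiated replicate 1 or 4 (0.168 and 0.0776). The synaptic list, where Syn1 rose (2.09 ± 0.23) and Syn2 was called with a bound of 0.986-fold, which shows no rise, at a median of 0.29, 0.10 blocked (camera adjusted p = 0.0192, range 0.00525 to adjusted p = 0.399 with an estimated correlation), lost it without the dim array (0.278). With 4 tissue scores as covariates endothelial (-0.08), phagocytosis (-0.02) and ribosomal medians (0.06) turned sign. The other 16 lists did not pass, and median and mean differed in sign for apoptosis (-0.09 and 0.16), eosinophil (0.09 and -0.12) and proteasome genes (-0.13 and 0.00).

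None of 13 cell type levels passed the exact test after adjustment in old mice, the B cell level going from 2.94 ± 0.207 to 1.24 ± 1.23 (exact permutation p = 0.0159, adjusted p = 0.0688). In old mice 1036 genes passed, 660 higher and 376 lower after irradiation, and 807 of them changed at least 2-fold. Blocking on slide, which rests on slide 4 and its single irradiated array, left limma calling 0 genes (1622 at an unadjusted p under 0.05). Of the 1036, 1035 kept their sign. The up and down counts were 501 and 548 with the scale over probes well above background on all arrays, 448 and 403 with quantile normalization and 2 and 14 with normexp. Leaving out single arrays gave 2482 (the dim array), 1907 (old irradiated replicate 2), 542 (old unirradiated replicate 2), 572 (replicate 5) and 626 (replicate 3).

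Across the 16548 genes, which are not independent replicates, the log2 fold changes of both ages correlated with r = 0.343 and rho = 0.370. No arrays were shared between the 2 comparisons. Of 3746 genes called at either age 3067 had the same sign (81.9%). Genes called higher at both ages numbered 486, against 101 for independent lists, and those lower at both 144, against 18.5. Opposite calls were found for 17 genes.

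**Figure D2:**
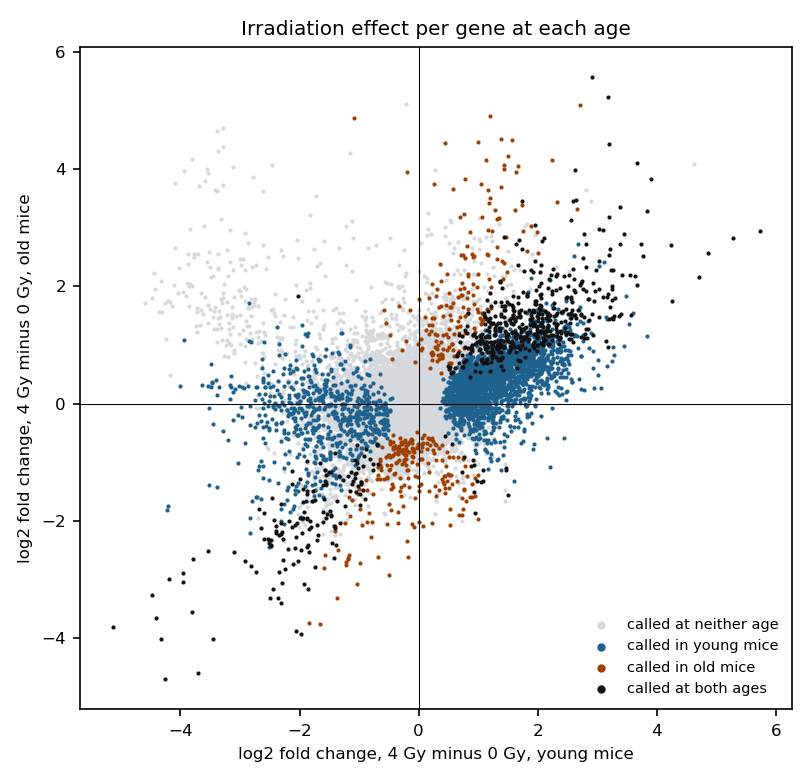
Log2 fold change of each tested gene after irradiation in young (horizontal axis) and old mice (vertical axis). Colours mark genes called at neither age, in young mice, in old mice or at both, the last group holding 486 genes higher and 144 lower at both ages.

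The third comparison set old against young unirradiated mice. Gzmk, a granzyme of memory T cells, was 43.4-fold higher (5.44 ± 0.66, adjusted p = 0.000214), measured on 4 of 5 young arrays, although its second probe read 1.5, and Pdcd1, the inhibitory receptor PD-1, 9.28-fold (3.21 ± 0.69, adjusted p = 0.00859). Lef1, a transcription factor of naive T cells, was 5.84-fold lower (-2.55 ± 0.31, adjusted p = 0.000214). The largest decreases were of liver secretory proteins: Alb, serum albumin, was at least 982-fold lower (adjusted p = 0.00299), with a level of 5.85 ± 4.18 in young mice, and Ahsg at least 715-fold lower. Of 27 hepatocyte genes, 25 were lower in old mice, and the level of that list was 3.37 ± 4.12 in young and -5.01 ± 0.39 in old mice (exact permutation p = 0.00794, adjusted p = 0.0317).

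Of 19 naive T cell genes, 6 were lower and none higher (10 lower and 1 higher adjusted over the list alone). Their median was -0.92, -0.62 blocked (camera adjusted p = 1.01e-06, range 7.31e-15 to adjusted p = 0.274 with an estimated correlation). Igfbp4 was 10.5-fold lower, measured on 4 of 5 old arrays, and Dapl1 7.34-fold. The T cell markers passed with 3 of 28 lower, Lef1, Trat1 and Tcf7, and their median of -0.26, 0.13 blocked (camera adjusted p = 0.003, range 5.19e-22 to adjusted p = 0.679 with an estimated correlation) turned sign when blocked, while Cd3e (-0.09 ± 0.43, adjusted p = 0.921) and Cd8a (0.44 ± 0.49, adjusted p = 0.606) did not pass. Of 31 effector, memory and exhaustion genes, 10 were higher (15 adjusted over the list alone). Their median was 0.87, 1.11 blocked (camera adjusted p = 4.82e-06, range 9.27e-09 to 0.823, adjusted p = 0.353 with an estimated correlation). The NK cell list passed with 3 of 27 higher, at a median of 0.65, 0.91 blocked (camera adjusted p = 0.00192, range 8.26e-10 to adjusted p = 0.67 with an estimated correlation). They were Ccl5, a T cell chemokine (2.17 ± 0.40), Sh2d1b1 and Klrg1 (1.54 ± 0.42). The B cell markers showed no called member among 25 (adjusted p = 0.969). Of 13 plasma cell and immunoglobulin genes, 3 were higher (4 adjusted over the list alone), with a median of 0.63, 0.80 blocked (camera adjusted p = 0.0103, range 0.000625 to adjusted p = 0.27 with an estimated correlation), among them Jchain, which joins antibody multimers (1.93 ± 0.59, adjusted p = 0.0466).

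Of 28 monocyte and macrophage markers, 21 were higher and none lower (the same numbers adjusted over the list alone). The list's median was 1.22, 1.31 blocked (camera adjusted p = 2.66e-11, range 1.25e-15 to adjusted p = 0.221 with an estimated correlation). Cd300e was 5.02-fold and Csf1r 2.14-fold higher. Of 31 mature neutrophil markers, 18 were higher (25 adjusted over the list alone), with a median of 1.20, 0.99 blocked (camera adjusted p = 2.66e-11, range 3.31e-16 to adjusted p = 0.274 with an estimated correlation), among them the formyl peptide receptor Fpr2 (2.50 ± 0.37). Of 17 granule genes of immature neutrophils, 4 were higher by either adjustment, with a median of 0.79, 0.22 blocked (camera adjusted p = 0.0167, range 0.00251 to 0.435, adjusted p = 0.353 with an estimated correlation). Of 19 eosinophil and basophil genes, 9 were higher and 1 lower (10 and 1 adjusted over the list alone). The median was 1.19, 0.95 blocked (camera adjusted p = 0.000437, range 1.17e-05 to adjusted p = 0.274 with an estimated correlation). The basophil protease Mcpt8 was 9.05-fold higher and was measured on 3 of 5 young arrays. Of 35 platelet and megakaryocyte genes, 20 were higher (31 and 1 lower adjusted over the list alone). Their median was 1.16, 1.47 blocked (camera adjusted p = 1.21e-11, range 1.43e-16 to adjusted p = 0.353 with an estimated correlation). Of 45 erythroid genes, 3 were higher by either adjustment, with a median of 1.08, 0.78 blocked (camera adjusted p = 3.28e-05, range 1.43e-09 to adjusted p = 0.67 with an estimated correlation), while Alas2, the first enzyme of erythroid haem synthesis, was at 0.59 ± 0.51 (adjusted p = 0.483).

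Of 28 inflammatory cytokine and NF-kB genes, 8 were higher (11 adjusted over the list alone). Their median was 0.77, 0.77 blocked (camera adjusted p = 4.2e-07, range 4.11e-09 to adjusted p = 0.274 with an estimated correlation). Il1b was 3.42-fold and Tnf 3.37-fold higher, and Il6, measured on 2 of 5 young arrays, was at 2.13 ± 0.41. Of 45 interferon-stimulated genes, 9 were higher (14 and 1 lower adjusted over the list alone), with a median of 0.47, 0.46 blocked (camera adjusted p = 0.00013, range 3.19e-06 to adjusted p = 0.274 with an estimated correlation), Oasl2 among them (1.86 ± 0.31). Of 26 oxidative stress response genes, 7 were higher (9 and 2 lower adjusted over the list alone). The members' median was 0.89, 0.63 blocked (camera adjusted p = 0.00236, range 1.02e-07 to adjusted p = 0.486 with an estimated correlation). They included Gsr, glutathione reductase (1.38 ± 0.25), and Hmox1, whose second probe read -0.14 against 1.62. Of 42 apoptosis genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone). The median was 0.32, 0.40 blocked (camera adjusted p = 0.0167, range 0.00614 to 0.888, adjusted p = 0.44 with an estimated correlation). The p53 targets did not pass (4 of 37 higher and 1 lower, adjusted p = 0.655), yet Phlda3 was 3.07-fold higher (1.62 ± 0.21, adjusted p = 0.00036), with Cdkn1a at -0.03 ± 0.44 (adjusted p = 0.978). Of 13 endothelial and fibroblast genes, 4 were lower and 1 higher (7 and 1 adjusted over the list alone). Their median was -1.80, -1.19 blocked (camera adjusted p = 0.000245, range 1.41e-05 to 0.796, adjusted p = 0.353 with an estimated correlation). The body cavity macrophage genes moved with them, 9 of 17 lower (median -2.82, -2.55 blocked), as did 1 of 13 mesothelial genes. Cell cycle genes passed with none of 35 called at a median of 0.50, 0.59 blocked (camera adjusted p = 0.042, range 0.0026 to adjusted p = 0.75 with an estimated correlation), and lost the call without young unirradiated replicate 1 or 4 (adjusted p = 0.0665 and 0.131) or old unirradiated replicate 2, 3 or 5 (0.0555, 0.0585 and 0.0984). The other 15 lists did not pass. Median and mean differed in sign for phagocytosis (0.32 and -0.04), FGF (0.33 and -0.11), DNA repair (-0.06 and 0.01) and oxidative phosphorylation genes (-0.01 and 0.05), and camera's direction was down for B cell (0.10 and 0.12) and synaptic genes (0.11 and 0.06).

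With 4 tissue scores as covariates the medians of effector (-0.14), NK cell (-1.27, and -0.52 with the hepatocyte score alone), cell cycle (-0.68) and apoptosis genes (-0.04) turned sign. The exact test on mean levels passed in 9 of 13 cell type lists after adjustment, with an adjusted p of 0.0129 for 8 of them. The neutrophil level was 1.12 higher in old mice, the monocyte level 0.992, the platelet level 1.04 and the erythroid level 1.01. The T cell level differed by -0.38 (exact permutation p = 0.167) and the B cell level by 0.116 (exact permutation p = 0.603).

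In all, 1623 genes passed, 1077 higher and 546 lower in old mice, and 1185 of them differed at least 2-fold, while the median of all genes was 0.103. With slide as a block, which joins slides 2 and 3, 4 genes passed, all lower, and 1610 of the 1623 kept their sign. The higher and lower counts became 505 and 817 with the scale over probes well above background on all arrays, 151 and 334 with the authors' own values and 147 and 175 with 4 other-tissue scores as covariates. Without the 5 arrays of high hepatocyte score, a setting chosen after seeing the data, 112 genes passed. Leaving out single arrays gave 3548 (the dim array), 682 and 761 (young unirradiated replicates 2 and 4) and 734, 840, 987 and 1001 (old unirradiated replicates 1 to 4).

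**Figure D3:**
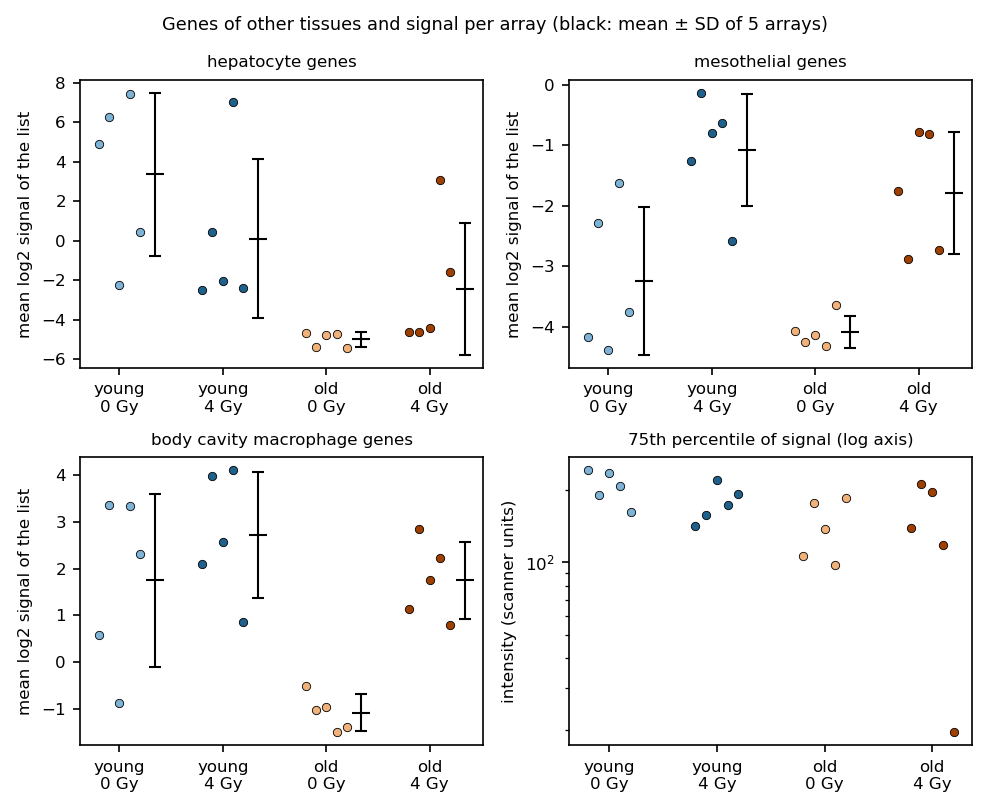
Mean log2 level per array of hepatocyte, mesothelial and body cavity macrophage genes, and the 75th percentile of the signal on a log axis, for the 4 groups of 5 arrays. The hepatocyte score ranged over 9.72 log2 units within young unirradiated mice, and the lowest 75th percentile signal was 19.7.

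The fourth comparison set old against young mice after irradiation. Interferon-stimulated genes were lower in old mice. Gzmk was 60.4-fold higher (5.92 ± 0.66, adjusted p = 0.000495), Pdcd1 14.2-fold (3.83 ± 0.69, adjusted p = 0.0158) and Lag3, an inhibitory receptor, 13.2-fold, Gzmk measured on 4 and Lag3 on 1 of 5 young arrays. The second probe of Gzmk read 2.21, and without old irradiated replicate 4 Pdcd1 stood at 2.90 and Lag3 at 2.73, both still called. Cd8a was 7.58-fold higher (2.92 ± 0.49, adjusted p = 0.00858). The antiviral genes Mx1 and Ifi204 were 2.88-fold and 2.83-fold lower (-1.52 ± 0.32 and -1.50 ± 0.22), and Ifit3 3.6-fold lower. Cdkn1a (-0.11 ± 0.44, adjusted p = 0.92), whose second probe read 0.53, and Phlda3 (-0.04 ± 0.21, adjusted p = 0.949) did not differ beyond the spread.

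Of 45 interferon-stimulated genes, 14 were lower and none higher (26 lower and 2 higher adjusted over the list alone). Their median was -0.81, -0.82 blocked (camera adjusted p = 3.76e-19, range 7.54e-32 to adjusted p = 0.00911 with an estimated correlation). The level of the list was 2.67 ± 0.198 in young and 2.01 ± 0.251 in old irradiated mice (exact permutation p = 0.00794, adjusted p = 0.0635). Of 31 effector, memory and exhaustion genes, 4 were higher and 1 lower (8 and 1 adjusted over the list alone). The list's median was 0.22, 0.79 blocked (camera adjusted p = 0.0277, range 4.14e-08 to 0.87, adjusted p = 0.869 with an estimated correlation). Monocyte markers (2 of 28 lower, 3 adjusted over the list alone) passed at a median of -0.40, -0.17 blocked (camera adjusted p = 0.00237, range 1.63e-07 to adjusted p = 0.83 with an estimated correlation), with Ccr2 at -1.37 ± 0.27 (adjusted p = 0.0262) and at -0.01 blocked. Erythroid and ribosomal genes passed with no called member, at medians of 1.03, 1.37 blocked (camera adjusted p = 3.25e-09, range 5.79e-12 to 0.892, adjusted p = 0.869 with an estimated correlation) and 0.44, 0.28 blocked (camera adjusted p = 1.95e-09, range 2.15e-12 to 0.958, adjusted p = 0.83 with an estimated correlation), and proteasome genes likewise at -0.28, -0.14 blocked (camera adjusted p = 0.0016, range 6.4e-07 to adjusted p = 0.605 with an estimated correlation). The ribosomal median turned with normexp (-0.12), quantile normalization (-0.05) and the authors' values (-0.21). On the dim array the erythroid level was 6.89, against 2.88 to 4.02 on the other old irradiated arrays, and without it the median was 0.35 (adjusted p = 0.00102). Of 13 plasma cell genes, 1 was higher, Derl3 (4 adjusted over the list alone). The median was 0.64, 0.80 blocked (camera adjusted p = 0.0131, range 0.000102 to adjusted p = 0.24 with an estimated correlation).

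The remaining calls in irradiated mice were weaker. The medians were -0.55, 0.81 blocked (camera adjusted p = 0.00685, range 9.84e-09 to adjusted p = 0.869 with an estimated correlation) for NK cell genes (none of 27 called, 1 higher adjusted over the list alone), 0.35, 1.41 blocked (camera adjusted p = 0.0113, range 1.06e-18 to adjusted p = 0.869 with an estimated correlation) for platelet genes (none of 35), 0.66, 0.12 blocked (camera adjusted p = 0.0113, range 1.14e-09 to adjusted p = 0.869 with an estimated correlation) for MHC class II genes (none of 11), -0.19, 0.14 blocked (camera adjusted p = 0.0401, range 0.000233 to adjusted p = 0.869 with an estimated correlation) for naive T cell genes (none of 19, 2 lower adjusted over the list alone), -0.16, 0.25 blocked (camera adjusted p = 0.0447, range 0.000115 to adjusted p = 0.869 with an estimated correlation) for apoptosis genes (none of 42) and -0.21, 0.11 blocked (camera adjusted p = 0.049, range 2.15e-05 to 0.895, adjusted p = 0.83 with an estimated correlation) for phagocytosis genes (1 of 49 lower by either adjustment). Platelet genes turned with normexp (-0.12), array weights (-0.19) and the authors' values (-0.08). NK cell, naive T cell, apoptosis and phagocytosis genes turned sign with slide as a block. These calls and those of effector and plasma cell genes each depended on single arrays. Without young irradiated replicate 1 the adjusted p was 0.0553 for NK cell, 0.0639 for apoptosis and 0.0584 for naive T cell genes, and without young irradiated replicate 3 it was 0.0542, 0.0542 and 0.06. Without young irradiated replicate 5 it was 0.0913, 0.117 and 0.0913, and 0.0976 for MHC class II genes. Without young irradiated replicate 2 it was 0.0905 for effector and 0.119 for phagocytosis genes, and without replicate 4 it was 0.205, 0.113 and, for platelet genes, 0.416. Without old irradiated replicate 1 it was 0.274 for effector and 0.289 for platelet genes, and without old irradiated replicate 2 it was 0.332 for MHC class II, 0.102 for NK cell, 0.112 for naive T cell and 0.0514 for plasma cell genes. Without old irradiated replicate 3 it was 0.219 for MHC class II, 0.0682 for apoptosis and phagocytosis and 0.065 for plasma cell genes. Without old irradiated replicate 4 it was 0.386 for effector, 0.0528 for naive T cell and 0.107 for phagocytosis genes. Without the dim array it was 0.0629 for NK cell, 0.477 for apoptosis, 0.168 for naive T cell, 0.151 for phagocytosis and 0.214 for platelet genes. For phagocytosis genes it was also 0.056 without young unirradiated replicate 4 and 0.0528 without old unirradiated replicate 1.

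After irradiation 93 genes passed, 57 higher and 36 lower in old mice, and 82 differed at least 2-fold. Blocked on slide, limma called 0 genes (186 at an unadjusted p under 0.05), 92 of the 93 kept their sign, and the fit of the 2 groups alone called 1. The higher and lower counts were 43 and 42 with the scale over probes well above background on all arrays, 14 and 2 with the authors' own values and 1 and 0 with normexp. Without single arrays the count was 32 (young irradiated replicates 1 and 3), 59 (replicate 2), 53 (replicate 5), 56 (old unirradiated replicate 2), 151 (old irradiated replicate 1) or 48 (old irradiated replicate 4). None of 13 cell type levels passed the exact test after adjustment. The other 19 lists did not pass, p53 targets at a median of 0.04 (adjusted p = 0.819), and median and mean differed in sign for neutrophil (0.02 and -0.02) and FGF genes (0.00 and -0.01). The age differences with and without irradiation correlated across genes with r = 0.408 and rho = 0.232, and 1017 of 1683 genes called in either had the same sign (60.4%). Genes called higher in both numbered 21, against 3.71 for independent lists, those lower in both 3, against 1.19, and opposite ones 9.

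The last comparison tested whether the response to irradiation differed between the ages, as the old minus the young log2 fold change. Interferon-stimulated and monocyte genes had negative values, meaning a smaller rise or a fall in old mice. Ms4a6d, a membrane protein of monocytes and macrophages, stood at 2.45 in young and -0.59 in old mice (interaction -3.03 ± 0.31, adjusted p = 0.000125). Fcgr1 stood at 1.94 and -0.69 (-2.63 ± 0.32, adjusted p = 0.000671), Ccr2 at 0.94 and -1.87 (-2.82 ± 0.39, adjusted p = 0.0013) and the antiviral gene Ifi204 at 2.47 and 0.05 (-2.42 ± 0.32, adjusted p = 0.0011). Mx1 stood at 3.26 and 0.72 (-2.53 ± 0.46, adjusted p = 0.0107). Of the p53 targets, Phlda3 rose by 3.67 and 2.02 (-1.66 ± 0.30, adjusted p = 0.0107), whereas for Cdkn1a the value was -0.08 ± 0.62 (adjusted p = 0.966).

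Of 45 interferon-stimulated genes, 17 had a negative interaction (28 adjusted over the list alone) and none a positive one, with a median of -1.30, -1.19 blocked (camera adjusted p = 2.51e-19, range 7.17e-34 to adjusted p = 0.00872 with an estimated correlation). Of 28 monocyte and macrophage markers, 10 were negative (21 adjusted over the list alone). Their median was -1.51, -1.32 blocked (camera adjusted p = 4.85e-16, range 3.83e-26 to adjusted p = 0.0287 with an estimated correlation). Of 28 inflammatory cytokine and NF-kB genes, 4 were negative (11 adjusted over the list alone), with a median of -0.95, -0.46 blocked (camera adjusted p = 3.56e-08, range 8.58e-11 to adjusted p = 0.266 with an estimated correlation), Il6 (-2.97 ± 0.57) and Tlr2 (-1.67 ± 0.34) among them. Of 31 mature neutrophil markers, 3 were negative (21 adjusted over the list alone). Their median was -1.31, -0.08 blocked (camera adjusted p = 3.4e-11, range 3.03e-18 to 0.743, adjusted p = 0.332 with an estimated correlation). Of 49 phagocytosis genes, 6 were negative (11 adjusted over the list alone), with a median of -0.37, -0.11 blocked (camera adjusted p = 0.0061, range 2.94e-05 to adjusted p = 0.332 with an estimated correlation), and of 42 apoptosis genes 2 (6 adjusted over the list alone). The members' median was -0.44, -0.23 blocked (camera adjusted p = 0.000427, range 3.04e-07 to 0.361, adjusted p = 0.332 with an estimated correlation). Of 19 naive T cell genes, 2 were positive, Als2cl and Tdrp (4 adjusted over the list alone). The median was 0.89, 0.96 blocked (camera adjusted p = 0.0021, range 5.65e-12 to adjusted p = 0.489 with an estimated correlation).

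Without a called member, T cell markers (2 positive adjusted over the list alone) had a median of 0.64, 0.96 blocked (camera adjusted p = 4.86e-05, range 1.82e-34 to adjusted p = 0.599 with an estimated correlation), NK cell genes of -1.09, 0.04 blocked (camera adjusted p = 2.91e-06, range 1.04e-10 to 0.743, adjusted p = 0.577 with an estimated correlation), platelet genes of -0.78, 0.06 blocked (camera adjusted p = 9.46e-06, range 3.53e-11 to 0.715, adjusted p = 0.599 with an estimated correlation) and proteasome genes of -0.40, -0.39 blocked (camera adjusted p = 0.00178, range 5.68e-06 to adjusted p = 0.332 with an estimated correlation). NK cell and platelet genes turned sign when blocked. With 4 tissue scores NK cell (0.71) and ribosomal genes (-0.10) turned too. Adjusted over the list alone, 2 platelet genes were negative. Eosinophil and basophil genes (1 of 19 negative, 4 adjusted over the list alone) had a median of -0.75, -0.20 blocked (camera adjusted p = 0.0151, range 0.000602 to 0.567, adjusted p = 0.489 with an estimated correlation) and lost the call without the dim array (adjusted p = 0.0545). Ribosomal genes had a median of 0.17, -0.06 blocked (camera adjusted p = 0.028, range 5.62e-06 to 0.852, adjusted p = 0.749 with an estimated correlation) and lost it without young unirradiated replicates 1, 3 or 5 (0.0597, 0.144 and 0.0658), young irradiated replicate 4 (0.0829), old unirradiated replicate 3 (0.0802) or old irradiated replicates 2 or 5 (0.175 and 0.624). The p53 targets (2 of 37 negative, adjusted p = 0.745), B cell markers (adjusted p = 0.201) and MHC class II genes (adjusted p = 0.486) did not pass, like 16 further lists. Median and mean differed in sign for FGF (-0.19 and 0.10) and p53 target genes (-0.07 and 0.04), and camera's direction was down for plasma cell genes (0.04 and 0.05).

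The interaction test called 288 genes, 55 positive and 233 negative, 280 of them at least 2-fold. With slide as a block 3 genes passed, all positive (210 at an unadjusted p under 0.05), and all 288 kept their sign. The positive and negative counts were 77 and 95 with the scale over probes well above background on all arrays, 5 and 6 with the authors' own values and 0 and 3 with normexp. Single arrays moved the count to 823 (without young irradiated replicate 4), 674 (old irradiated replicate 1), 88, 129 and 170 (young unirradiated replicates 1, 2 and 4), 113, 117 and 102 (young irradiated replicates 1, 3 and 5), 120, 71 and 74 (old unirradiated replicates 1, 2 and 3) and 181 (old irradiated replicate 4).

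**Figure D4:**
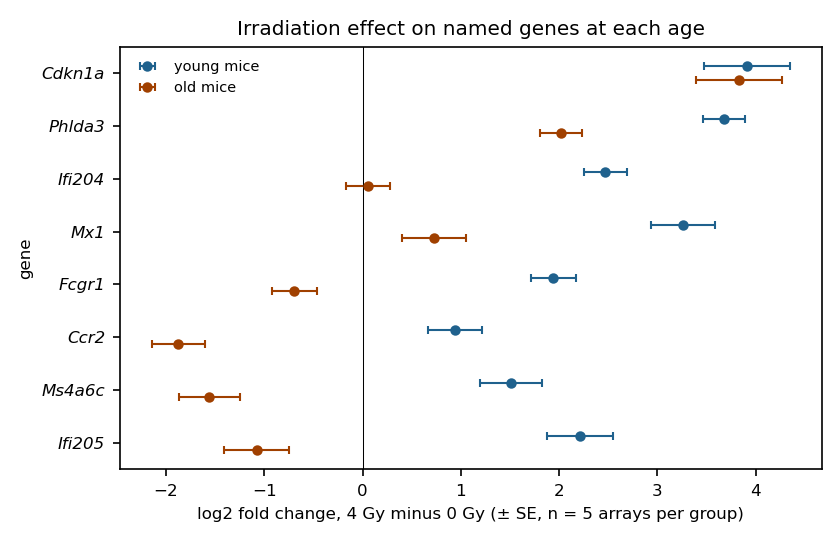
Log2 fold change after irradiation in young and old mice for 8 genes, with bars showing the SE from limma (5 arrays per group). The value of Ifi204 was 2.47 in young and 0.05 in old mice, and that of Cdkn1a 3.91 and 3.83.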

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

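The tests of the hepatocyte pattern, the dim array and slide tests of the interferon-stimulated genes, the dim array test of the mesothelial genes, the slide and paired tests of mean levels and the interaction splits by young pairs were chosen only after the result was seen.

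For irradiation in young mice, 1 of 100 splits of the arrays, the real one, gave 3357 genes, and the highest other, parting fewer pairs, 2528. The 12 splits that part all pairs gave at most 0 besides the real one. They are too few to exclude chance, and the 100 ignore the pairing that was assumed. For irradiation in old mice again 1 of 100 gave 1036 and the next 911, so chance is only unlikely. For age in unirradiated mice 1 of 100 gave 1623 and the rest 0. Chance is unlikely there as well, but 100 splits cannot exclude it. For age in irradiated mice 6 of 100 splits gave at least 93 genes, the highest 2957, and for the interaction 6 of 100 gave at least 288, the highest 3110. Chance cannot be excluded there, and splits calling so many more genes than the real one point to a structure of the samples. The 15 interaction splits that part all young pairs reached 3110 as well. The first principal component held 38.9% of the variance and correlated with the hepatocyte score (absolute r = 0.968), but whether the splits follow it was not tested.

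Liver transcripts were higher in young than in old unirradiated mice. The hepatocyte score ranged over 9.72 log2 units within young unirradiated mice, and its genes moved together over those arrays (median pairwise r = 0.997), which fits liver cells or RNA carried into some samples at blood collection. The same range of 9.72 lay within the 4 arrays of slide 1, all of one group, which argues against slide. Age stays open: old and young irradiated mice gave an exact permutation p of 0.365, which decides neither way. Of the 2 old irradiated arrays above the young irradiated median, replicate 4 had a score of 3.08 with 28 hepatocyte genes above background, and the dim array -1.57 with 8. Liver material carried over is a candidate explanation, and 25 of 27 genes being lower with age cannot be told apart from it by so few samples.

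Interferon-stimulated genes rose more in young than in old mice, with a median interaction of -1.30. Without the dim array it was -1.30 (camera adjusted p = 6.53e-21), which argues against the dim array. With slide as a block it was -1.19 (-1.22 for the mean level), from single young unirradiated and old irradiated arrays. With the monocyte marker score as a covariate it was -1.04 (camera adjusted p = 1.76e-17), but markers are not cell counts. Slide and monocyte share stay open, age itself was not tested, and 6 of 100 splits called as many interaction genes.

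Mesothelial and body cavity macrophage levels were higher after irradiation in old mice (adjusted p = 0.0127 for both). In young mice the levels did not pass (2.16, adjusted p = 0.0635, and 0.970, adjusted p = 0.426), although the first was higher in 5 of 5 pairs (exact paired permutation p = 0.0625, the smallest possible) and the second in 4 (0.312). Their scores deviated together from their group means over the 20 arrays (r = 0.690, permutation p = 0.0111, rho = 0.627, permutation p = 0.0200, r = 0.569 without the 2 farthest arrays), which fits cells of the body cavities carried in at blood collection. With slide as a block the mesothelial level differed by 3.03 ± 1.18 (SE) in young mice, from a single unirradiated array, so slide stays open. Slide stays open too for the mesothelial level in old mice (2.28 ± 1.18) and the macrophage level in young (0.555 ± 1.60) and old mice (2.41 ± 1.60), whose 95% intervals reach 0. The medians over both lists (1.29 and 2.76) decide nothing, since they carry no spread and mix the lists. The smallest gap between the 4 other old irradiated and the old unirradiated arrays was 0.758 (exact permutation p = 0.00794), which argues against the dim array in old mice. An effect of irradiation on such cells may stand behind it too and was not tested.

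Single arrays stood far from the others of their group by the gap over the range, which chance gives in about 1 in 20 groups. This was so in 1 of 8 groups of array measures (12.5%), 8 of 148 of list levels (5.41%) and 23 of 380 of genes (6.05%). On the dim array 33.3% of spots were well above background, against 51.5% to 55.7% (0.812), with the erythroid level at 6.89 (0.714) and the DNA repair level at -0.47 (0.894). The DNA repair level of old unirradiated replicate 5 was 0.15 (0.751), the synaptic level of young unirradiated replicate 5 -1.23 (0.923), the ribosomal level of young irradiated replicate 4 7.24 (0.757) and the oxidative phosphorylation level of old unirradiated replicate 1 4.28 (0.834). The muscle level of old irradiated replicate 3 was 2.62 (0.808) and the endothelial and fibroblast level of replicate 2 -2.40 (0.747).

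Among genes the ratio of gap to range was 0.724 for Alas2 and 0.849 for Mdm2 on the dim array, 0.751 for Cd34 and 0.784 for Jchain on old irradiated replicate 2, 0.721 for Dapl1, 0.760 for Pdcd1 and 0.813 for Rtp4 on replicate 4, and 0.730 for Gzmb on replicate 1. On young irradiated replicate 4 it was 0.810 for Als2cl, 0.777 for Igfbp4, 0.856 for Mx1 and 0.837 for Phlda3, and on replicate 2 it was 0.798 for Csf1r, 0.848 for Il6, 0.789 for Slpi and 0.743 for Tdrp. It was 0.777 for Hmox1 on young irradiated replicate 1, 0.780 for Mcpt8 on replicate 5, 0.778 for Hmox1 and 0.733 for Jchain on young unirradiated replicates 4 and 2, and 0.850 for Ddit3, 0.733 for Cd79a and 0.775 for F2rl2 on old unirradiated replicates 3, 3 and 4.

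The response to irradiation differed between the ages by the interaction test in 288 genes, for which chance was not excluded, and in 13 lists: T cell (median 0.64), naive T cell (0.89), NK cell (-1.09), neutrophil (-1.31), monocyte (-1.51), eosinophil (-0.75), platelet (-0.78), apoptosis (-0.44), phagocytosis (-0.37), interferon-stimulated (-1.30), inflammatory (-0.95), ribosomal (0.17) and proteasome genes (-0.40). With an estimated correlation only the interferon-stimulated (adjusted p = 0.00872) and monocyte lists (0.0287) passed, the others lying from 0.266 to 0.749, and the NK cell, platelet and ribosomal medians turned sign when blocked. Among genes named here it differed for Als2cl (2.32), Tdrp (2.03), Ms4a6d (-3.03), Il6 (-2.97), Ccr2 (-2.82), Fcgr1 (-2.63), Mx1 (-2.53), Ifit3b (-2.47), Ifi204 (-2.42), Ifit3 (-2.30), Fpr2 (-2.28), Oasl2 (-2.08), Ifit1 (-2.06), Rtp4 (-1.88), Gsr (-1.72), Tlr2 (-1.67), Phlda3 (-1.66), Fcgr4 (-1.52) and Gata2 (-1.36).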

How the results depend on the processing

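Fits without arrays of high hepatocyte score or with tissue scores were chosen after seeing the data. Signal over background limits what the dim array adds: its 75th percentile was 19.7, against 97.5 to 242. Across settings other than leaving out single arrays, 2379 list results stayed on their side of the threshold, 236 passed it, 207 missed it and 48 turned camera's direction, and for named genes these numbers were 3782, 46, 959 and 9 (turned sign). Leaving out single arrays gave 3025, 117, 56 and 2 for lists. The cause was not tested for any change below, except that fewer probes, genes or arrays enter where a setting says so.

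Genes called for irradiation in young mice numbered 908 with normexp, 100 with slide as a fixed block, 6244 with slide as a random block (correlation -0.195, which narrows errors between slides), 8366 with array weights, 199 with 4 tissue scores and 1932 at an unadjusted p under 0.001. Single arrays left out gave 2664 to 5042. For irradiation in old mice the count was 16 with normexp, 632 without a filter on dim probes, 599 with probes well above background on all arrays, 0 with slide as a fixed block (limma, 1622 at an unadjusted p under 0.05), 4299 with slide as a random block and 644 with only the arrays compared. It was 3705 with array weights, 406 with the authors' values, 673 at an unadjusted p under 0.001 and 2692 without arrays of high hepatocyte score and the dim array. Single arrays gave 542 to 2482.

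For age in unirradiated mice the count was 33 with normexp, 825 without a filter, 1010 with probes well above background on all arrays (931 higher and 79 lower), 4 with slide as a fixed block, 6107 with slide as a random block, and 4800 with only the arrays compared. It was 6928 with array weights, 485 with the authors' values, 152 with the hepatocyte score, 322 with 4 tissue scores, 792 at an unadjusted p under 0.001, 112 without arrays of high hepatocyte score and 545 without those and the dim array. Without single arrays it was 682 to 3548. For age in irradiated mice it was 1 with normexp, 55 without a filter, 46 with probes well above background on all arrays, 0 with slide as a fixed block (limma, 186 at an unadjusted p under 0.05), 2587 with slide as a random block, and 1 with only the arrays compared. It was 568 with array weights, 16 with the authors' values, 313 with the hepatocyte score, 155 with 4 tissue scores, 185 at an unadjusted p under 0.001, 16 without arrays of high hepatocyte score and 68 without those and the dim array. Single arrays moved it from 32 to 151.

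For the interaction it was 3 with normexp, 172 with scaling over probes well above background on all arrays, 54 without a filter, 177 with a floor, 3 with slide as a fixed block, 4409 with slide as a random block, and 4404 with array weights. It stood at 11 with the authors' values, 57 with the hepatocyte score, 97 with 4 tissue scores, 6 without arrays of high hepatocyte score and 41 without those and the dim array. Single arrays left it at 71 to 823. The median of all genes moved most in irradiated old mice without a filter (0.250) and in young mice with scaling over probes well above background on all arrays (-0.332). The correlation of the irradiation effect between ages was 0.670 with slide as a fixed block and 0.645 without arrays of high hepatocyte score and the dim array (0.228 to 0.457 without single arrays), and that of age effects ran from 0.092 to 0.531 without single arrays. List calls, 77 at first, numbered 10 with an estimated correlation, 57 with fry and 76 to 85 without single arrays, and marker level calls, 15 at first, 23 with the median of members.

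With the replicate block, which changed no other count by over 1.5 times, age in irradiated mice gave 45 genes against 93 and lost 10 of 32 named genes and the effector list (adjusted p = 0.0594), while B cell and cell cycle lists passed (0.0408 and 0.0423). In young mice, where the numbers pair the arrays, the paired fit changed no list call and lost 4 of 70 named genes (Xrcc6, Rps15, Rps3 and Cd79a, the last at an adjusted p of 0.0658). Elsewhere pairing was not assumed. Same-numbered arrays correlated from -0.530 to 0.407 for irradiation in old mice (1 of 5). The range was -0.176 to 0.0291 for age in unirradiated mice (0 of 5). In irradiated mice it was 0.00441 to 0.611 (2 of 5, with 4 of 5 over 0.1).

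Lists whose camera direction turned are given with their medians, which turned sign too except where stated. With normexp they were oxidative stress after irradiation in old mice (-0.36) and, for age in irradiated mice, platelet (-0.12), ribosomal (-0.12) and heat shock genes (-0.16). With quantile normalization they were ribosomal genes for age (-0.12 in unirradiated and -0.046 in irradiated mice). With slide as a fixed block they were, for age in irradiated mice, naive T cell (0.14), NK cell (0.81), neutrophil (0.71) and MHC class II genes (0.12), the last 2 with a median of unchanged sign, apoptosis (0.25) and phagocytosis genes (0.11), and for the interaction B cell (-0.68), immature neutrophil granule (0.16), platelet (0.062) and ribosomal genes (-0.055). With array weights they were oxidative stress after irradiation in old mice (-0.26), platelet (-0.19) and cell cycle genes (-0.53) for age in irradiated mice and erythroid genes for the interaction (-0.80). With the authors' values they were platelet and megakaryocyte genes, age in irradiated mice (-0.079), and ribosomal genes there (-0.21). Without single arrays the oxidative stress median in old mice ran from -0.29 to 0.15 and the erythroid interaction from -0.60 to 0.55, both lowest without the dim array.

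Without arrays of high hepatocyte score the oxidative phosphorylation median for age in unirradiated mice was 0.30. Without those and the dim array it was 0.30 again, with oxidative stress after irradiation in old mice at -0.32, platelet (-0.17) and cell cycle genes (-0.44) for age in irradiated mice and erythroid genes for the interaction (-0.61). With the hepatocyte score, NK cell (-0.52), oxidative phosphorylation (0.48) and endothelial genes (-0.068, the sign of the median unchanged) turned for age in unirradiated mice. With 4 tissue scores, erythroid (0.55) and ribosomal genes (0.13) turned after irradiation in young mice. Those turned in old mice were erythroid (0.78), phagocytosis (-0.021), ribosomal (0.057) and endothelial genes (-0.084). For age in unirradiated mice they were effector (-0.14), NK cell (-1.27), cell cycle (-0.68), apoptosis (-0.037) and oxidative phosphorylation genes (0.62), and for the interaction B cell (-0.64), effector (0.80), NK cell (0.71), MHC class II (-0.86), cell cycle (0.83) and ribosomal genes (-0.10). Named genes that turned there were Rps15 (0.19) and Rps3 (0.030) in young and Cd8a (1.5) and C1qc (-0.014) in old irradiated mice, and Klrg1 (-0.49), Cd177 (-0.034), Sptb (-0.33) and F2rl2 (-0.29) for age in unirradiated mice, as did the log2 fold change of Bid, age in unirradiated mice (-0.088). With the median of members, the immature neutrophil granule level moved by 0.54 in young mice.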

Other observations

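The test of effector against T cell genes was chosen only after the result was seen, as were the genes Alb and Myh6. The effector, memory and exhaustion genes of T cells set against the T cell markers of the same array lay at -1.93 ± 0.288 in young and -0.456 ± 0.248 in old unirradiated mice, a difference of 1.47 (n = 5, exact permutation p = 0.00794), while the T cell level itself differed by -0.38.

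The B cell level of the 5 old irradiated arrays was 0.388, 2.66, 2.48, 0.136 and 0.515, against 2.94 ± 0.207 in old unirradiated mice, and their MHC class II level was 1.59, 3.69, 3.46, 1.60 and 1.37. The p53 level of the same arrays was 0.876, 0.930, 0.964, 0.988 and 1.16, and the interferon-stimulated level 1.93, 1.85, 2.22, 1.72 and 2.31. The hepatocyte marker Alb lay at 7.48, 8.84, -0.14, 9.80 and 3.26 on the 5 young unirradiated arrays, at 8.93 on young irradiated replicate 4 and at 4.72 on old irradiated replicate 4. The heart muscle gene Myh6 lay at 5.82 on old irradiated replicate 3.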
